A study of Mus musculus with 6 samples.

How the data were processed

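The series measured RNA from mouse bone marrow-derived macrophages by sequencing. Per the labels' protocols, marrow cells were cultured for 6 days with 10% serum and M-CSF at 25 ng/ml. They then received K7M2 vesicles (10 µg) or PBS for 24 h. Total RNA was isolated and libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols. The strand setting is not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty. The authors deposited FPKM values, 1 table per library, with 26883 gene rows. The submitters' processing notes name CASAVA 1.8, HISAT2 2.1.0, StringTie 1.3.4b, edgeR and the build GRCm38, without the role of each. Groups and replicate numbers came from the sample titles, 3 libraries per group.

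A row without a value (1) was left out, and where a symbol was repeated the row with the highest mean was kept. This dropped 47 rows and left 26835 genes. Gene lengths and positions came from GENCODE release M21 on GRCm38, matched by symbol for 26661 genes (99.4%). FPKM times exon length fell near whole multiples of 1 step per library. Between 72.3% and 73.2% of values worth at most 20 reads were whole within 0.1, where chance gives 20%. The step gave implied totals of 21987240, 21335004 and 25689534 reads for PBS replicates 1 to 3 and 24080512, 22182449 and 24070879 reads for K7M2-EV replicates 1 to 3. Genes at 1 FPKM or more numbered 12864 to 13173 with PBS and 11878 to 12216 with vesicles. Small and structural RNAs took 15.7% to 17.4% of reads. Fth1 alone took 2.26% to 2.59% with PBS and 7.4% to 8.3% with vesicles. None of 15 housekeeping genes was listed at 0. Among them Gapdh, named after its values were seen, was at only 2.29 ± 0.154 FPKM with PBS and 3.55 ± 0.137 FPKM with vesicles. The check for 0 therefore does not show that no gene is listed too low.

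The design fixed before the data were examined assumed counts, with a fallback for normalized values that was used here. Genes with at least 1 FPKM in at least 3 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust settings, statmod 1.5.0) and no further scaling. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 over 13009 genes. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Gene lists (34, fixed before the data were examined) were tested with limma's camera at a preset inter-gene correlation of 0.01 where at least 5 members were tested. This left 30 lists, and their p-values were adjusted over those lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and plots.

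Named genes followed a rule fixed beforehand. It took the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 FPKM and no overlap between groups, skipping predicted or clone names. It added the called members of each list with the largest changes, and 11 polarization genes with 3 mesenchymal genes whatever their result. Genes named outside the rule are said to have been chosen after their values were seen.

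Same-numbered libraries deviated together from their group means, with correlations of 0.407, 0.206 and 0.32 across genes. Every library correlated best with its own number, so the numbers were taken to pair the samples, from the data and not from a label. This basis is weak, because 3 libraries per group allow few matchings and deviations from a group mean are not independent. Results with the replicate block depend on it. The planned fit without a block stayed the main one, and a fit with the replicate number as a block was an alternative.

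The steps were tested on simulated data for K7M2-EV against PBS, drawn for 12538 genes passing the filter with 3 libraries per group. For 200 changed genes, 58.2% of 1.5-fold, 92.5% of 2-fold and 95.5% of 4-fold changes were recovered. Of the simulated calls 9.89% were false, above the nominal level, and none of 100 unchanged lists was called. Each gene was drawn independently, so these lists held no correlation between genes. The simulation thus cannot show how often correlated lists are called falsely. It was not repeated, and it changed far fewer genes than the 54% called in the real data. Other pseudocounts, filters, scalings, a voom fit and left-out libraries were tried as alternatives.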

Results

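RNA was sequenced from bone marrow-derived macrophages of BALB/c mice. These are primary cells grown out of marrow from 5- to 8-week-old animals with the growth factor M-CSF. The cells had been exposed for 24 h to 10 µg of extracellular vesicles from K7M2, a mouse osteosarcoma cell line, or to PBS (phosphate-buffered saline). Each of the 2 groups held 3 biological replicates, described by the submitters as independent experiments, so that 6 libraries were compared. The values are FPKM (fragments scaled to transcript length and library total) for 26883 rows of gene symbols. The spacing of the low values implied between 21335004 and 25689534 reads per library. At 1 FPKM, a gene of 2 kb was then backed by 42.7 to 51.4 reads, a counting error of at most 15.3%. The comparison asked how osteosarcoma vesicles change gene expression, and with it the polarization state, of macrophages.

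Saa3, which encodes an acute-phase serum amyloid, went from 0.276 ± 0.0426 FPKM with PBS to 1741 ± 266 FPKM with K7M2 vesicles (SD, n = 3 per group). Il1b, which encodes interleukin-1β, went from 0.655 ± 0.307 to 331 ± 11.7 FPKM. The mannose receptor gene Mrc1 fell from 43.7 ± 4.04 to 3.59 ± 1.18 FPKM. Emp1, which encodes an epithelial membrane protein, fell from 74.7 ± 1.38 to 1.18 ± 0.542 FPKM. On GRCm38, Saa3 lies on chromosome 7 at 46711998 to 46715700 and Il1b on chromosome 2 at 129364570 to 129371139, both on the minus strand.

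Of 13009 genes tested, 2395 were higher and 4631 were lower with vesicles (limma, Benjamini-Hochberg adjusted p under 0.05). With a log2 fold change of at least 1 in size as well, 600 were higher and 893 lower. In 8302 genes, 63.8% of those tested, the libraries of the 2 groups did not overlap, where chance gives 10%. The first principal component held 84.3% of the variance and separated the groups. The median log2 fold change of all genes was -0.12, and the excess of lower genes depended on the scaling. After median-of-ratios scaling, which brought that median to -0.0024, 3445 genes were higher and 3376 lower, and after quantile normalization 3136 and 3283. Both settings bring the median near 0 by construction, so they cannot show whether the excess is real. Rescaling to reads in nuclear protein-coding genes other than Fth1 gave 2459 higher and 4526 lower, but its factors ran only from 0.9887 to 1.008. The voom fit on approximate reads gave 2370 and 4645, and it kept the library totals implied by the FPKM. Both leave the library scaling nearly as it was, so they cannot show whether the excess is real either.

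**Figure D1:**
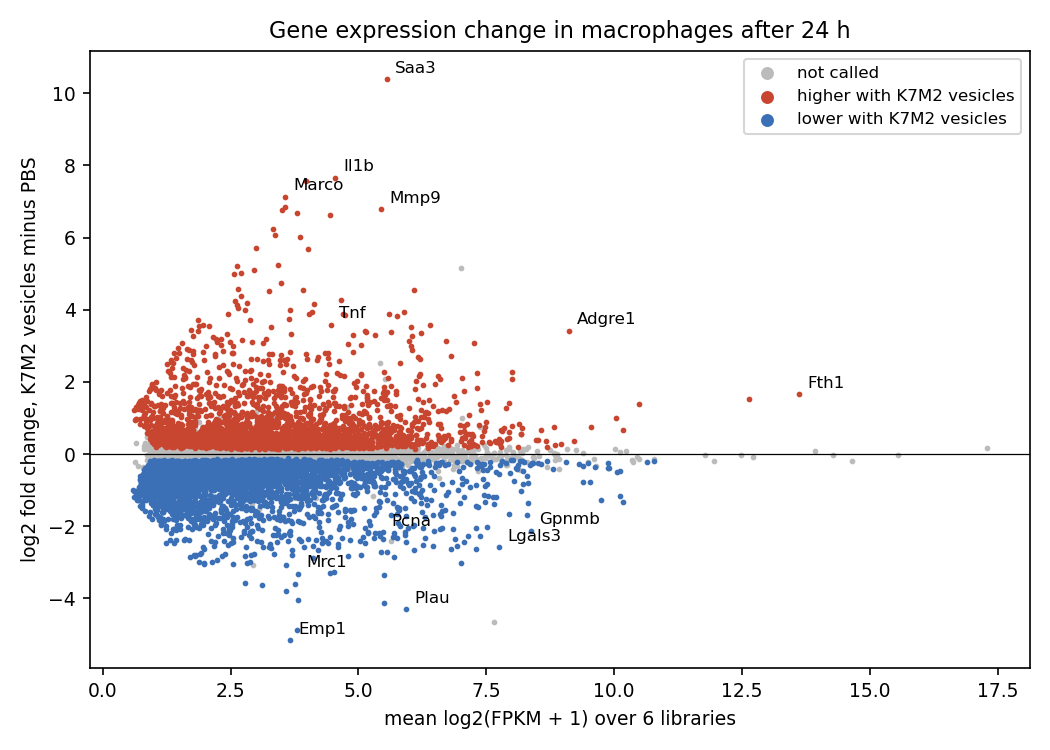
Log2 fold change of each of the 13009 tested genes (vertical axis, K7M2 vesicles minus PBS, on the log2(FPKM + 1) scale) against its mean log2(FPKM + 1) over the 6 libraries (horizontal axis). Points are coloured by call at an adjusted p of 0.05, and the highest point is Saa3 at 10.40.

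Besides Saa3 and Il1b, the 12 largest rises among well-expressed genes included Acod1, whose enzyme makes itaconate. It had a log2 fold change of 7.57 and reached 216 ± 17.3 FPKM. The formyl peptide receptor genes Fpr1 and Fpr2 had log2 fold changes of 6.86 and 6.67. Marco, a scavenger receptor gene, was listed at 0 in all 3 PBS libraries and at 139 ± 1.67 FPKM with vesicles. The gelatinase gene Mmp9 rose from 3.42 ± 2.08 to 459 ± 42.0 FPKM and the chemokine gene Ccl5 from 1.21 ± 0.470 to 219 ± 61.0 FPKM. Cfb, Hp, H2-M2 and Siglece completed this group with log2 fold changes of 6.02 to 6.76.

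The 12 largest falls, besides Emp1 and Mrc1, included Plau, which encodes urokinase, from 274 ± 40.7 to 12.9 ± 2.12 FPKM. Atp6v0d2, a subunit gene of the vacuolar proton pump, fell from 190 ± 18.1 to 9.85 ± 1.34 FPKM. Mamdc2, Cxcr4, Xylt1, Rgs2, Pcp4l1 and Il7r had log2 fold changes between -4.89 and -3.30. The histone genes Hist2h3c1 and Hist1h2af had values of -4.06 and -3.35. They belong to a multigene family whose near-identical members share reads, and Hist2h3c1 had an SD of 4.55 around a mean of 3.89 FPKM with vesicles.

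Genes of inflammatory, or M1-type, activation rose as a group. Of 14 tested, 9 were higher, 2 lower and 3 not called (median log2 fold change 1.78, camera adjusted p = 6.19e-06). The call was lost with an estimated correlation between genes (adjusted p = 0.156). Il1a, Socs3 and Tnf rose by 5.09, 4.52 and 3.59 on the log2 scale, and Tnf, the tumour necrosis factor gene, went from 5.34 ± 0.555 to 75.7 ± 10.1 FPKM. Il6 rose and stayed low, at 0.0111, 0 and 0.00953 FPKM with PBS and 1.61, 2.13 and 1.82 FPKM with vesicles. The co-stimulator gene Cd80 fell by 0.88. Nos2, which encodes inducible nitric oxide synthase, was below the filter. It was listed at 0 in the PBS libraries and at 0.256, 0.536 and 0.274 FPKM with vesicles. Cd86 was also below it, at 0.702, 0.392 and 0.375 FPKM with PBS and 0.347, 0.271 and 0.187 FPKM with vesicles.

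Genes of alternative, or M2-type, activation moved both ways, with 3 of 8 higher, 5 lower and a median log2 fold change of -1.46 (camera adjusted p = 0.775). Besides Mrc1, the β-glucan receptor gene Clec7a fell from 60.0 ± 16.1 to 8.94 ± 0.254 FPKM and the kinase gene Matk by 2.09 on the log2 scale. Il10, an anti-inflammatory cytokine gene, rose from 0.457 ± 0.0676 to 5.18 ± 1.11 FPKM. The arginase gene Arg1 was near the floor, at 0.0174, 0.143 and 0.0149 FPKM with PBS and 0.0792, 0.189 and 0.111 with vesicles. Cd163, a haemoglobin scavenger receptor gene, was at 0.0916, 0.155 and 0.0672 FPKM and at 0.0179, 0.0195 and 0.0179 FPKM. Retnla, which was to be named whatever its result, was not analysed here.

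**Figure D2:**
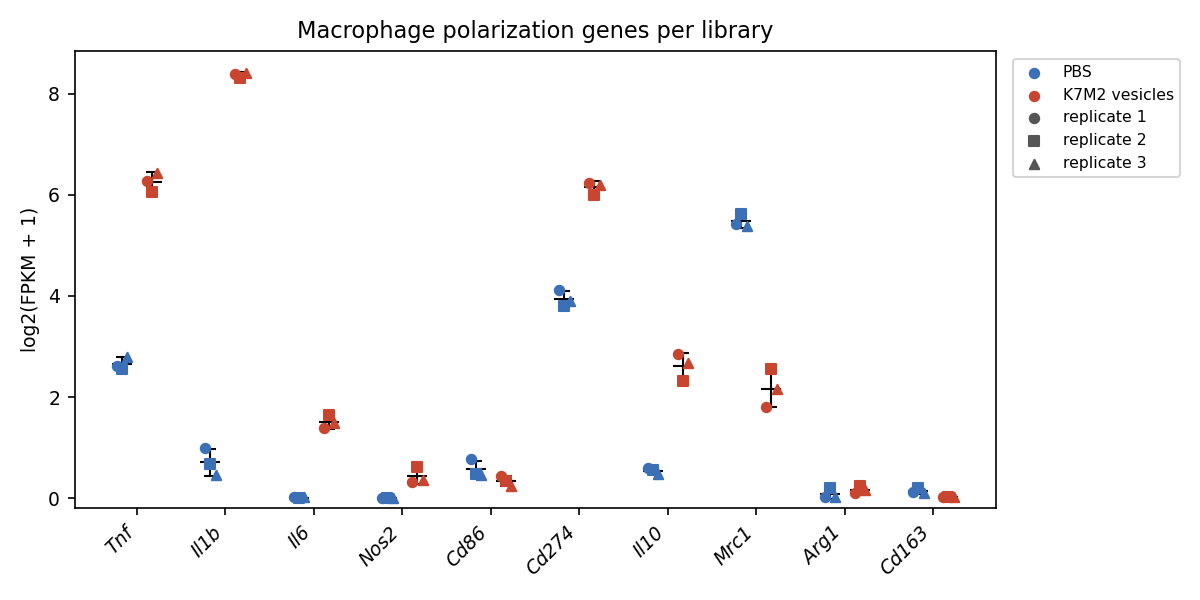
Expression of 10 macrophage polarization genes (horizontal axis) as log2(FPKM + 1) (vertical axis) in each library, with PBS in blue, K7M2 vesicles in red and the replicate number shown by the symbol. Black bars give the mean and SD of 3 libraries, and Mrc1 falls from 43.7 to 3.59 FPKM while Tnf rises from 5.34 to 75.7 FPKM.

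Of the 20 genes fixed beforehand as strongly induced by bacterial endotoxin, 16 were higher, 1 lower and 3 not called. Adjusted over the list alone, 17 were higher. The median log2 fold change was 3.03 (camera adjusted p = 1.44e-13), and this was the only list still called with an estimated correlation (adjusted p = 0.033). Beyond Saa3, Acod1, Fpr1 and Marco, which belong to it, the urokinase receptor gene Plaur fell by 1.21. All 21 members of the NF-κB feedback list rose (median 1.89, camera adjusted p = 7.6e-17, adjusted p = 0.156 with an estimated correlation). Sod2, a mitochondrial superoxide dismutase gene, went from 13.1 ± 1.22 to 329 ± 19.2 FPKM, and the inhibitor gene Nfkbia from 14.2 ± 0.974 to 234 ± 23.2 FPKM. Of 14 chemokine ligand genes, 12 rose and 1 fell (median 2.43, camera adjusted p = 6.52e-08, adjusted p = 0.0724 with an estimated correlation). Cxcl3, Cxcl5 and Cxcl1 rose by 5.22, 4.57 and 4.38, and Cxcl14 fell by 0.70, a call lost without both libraries of replicate 1 (adjusted p = 0.0647) or 3 (0.0976).

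All 29 type I interferon-stimulated genes tested rose, with a median log2 fold change of 1.48 (camera adjusted p = 2.71e-19, adjusted p = 0.198 with an estimated correlation). The ubiquitin-like modifier gene Isg15 went from 6.07 ± 0.883 to 101 ± 20.6 FPKM, and Usp18 and Ifit1 rose by 3.18 and 3.11. Among 14 genes of the interferon-γ GTPase list, 12 rose and 1 fell (median 1.29, camera adjusted p = 6.93e-08, adjusted p = 0.326 with an estimated correlation). Socs1 and Gbp2 rose by 2.98 and 2.84, while Irf1 fell by 0.47, a call lost without both libraries of replicate 1 (adjusted p = 0.0763) or 3 (0.0545). For MHC class I presentation, 12 of 15 genes rose, 13 when adjusted over the list alone (median 0.81, camera adjusted p = 6.93e-08, adjusted p = 0.156 with an estimated correlation). Psme2 and Tapbp rose by 1.67 and 1.32. In the MHC class II list, 5 of 10 rose and 2 fell, with a median of 0.91 (camera adjusted p = 0.0804). After median-of-ratios scaling or quantile normalization only 1 was lower. With the replicate number as a block, that list was called (adjusted p = 0.00982). In the fit without a block, its adjusted p was 0.694 with an estimated correlation. H2-Ab1 rose by 1.58, a call lost without both libraries of replicate 3 (adjusted p = 0.0582), and Ifi30, a lysosomal thiol reductase gene, fell by 0.82. For H2-Eb1 the change of 1.11 lost its call when PBS replicate 2 or 3 or K7M2-EV replicate 1 or 3 was left out, with values from 0.82 to 1.18. It also lost the call with quantile normalization (adjusted p = 0.0537), with no filter (0.0745) and without both libraries of replicate 1 (0.0937) or 3 (0.189).

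Genes of cell division fell together. All 24 mitotic genes were lower (median log2 fold change -1.71, camera adjusted p = 2.1e-06, adjusted p = 0.524 with an estimated correlation). Mki67, a proliferation marker, fell from 40.7 ± 8.77 to 7.11 ± 2.25 FPKM, and Kif11 and Ccnb2 fell by 2.33 and 2.32. All 23 DNA replication genes tested were lower (median -0.997, camera adjusted p = 1.96e-05, adjusted p = 0.524 with an estimated correlation). Pcna, the replication clamp gene, fell from 93.4 ± 6.98 to 20.2 ± 0.287 FPKM. In both groups the median mitotic gene was highest in replicate 2, at 8.87 FPKM with PBS and 2.32 FPKM with vesicles. That is also the replicate with the highest mesenchymal transcripts.

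All 14 tested genes of fatty-acid uptake, storage and PPAR targets fell (median -1.42, camera adjusted p = 1.94e-06, adjusted p = 0.156 with an estimated correlation). Fabp4, a fatty-acid binding protein gene, fell by 3.06 on the log2 scale to 0.378 ± 0.104 FPKM and the nuclear receptor gene Pparg from 12.3 ± 0.413 to 1.43 ± 0.268 FPKM. Gpnmb, an abundant glycoprotein gene, fell from 689 ± 43.7 to 158 ± 20.9 FPKM. Of 28 lysosomal genes, 20 fell and 5 rose (median -0.57, camera adjusted p = 0.0216, adjusted p = 0.69 with an estimated correlation). Psap, which encodes the precursor of the saposins, fell from 1832 ± 87.9 to 729 ± 14.2 FPKM, while the protease gene Ctsc rose by 1.32. Phagocytic receptors and bridging molecules split into 8 higher and 14 lower of 24 (median -0.70, mean -0.04, camera adjusted p = 0.775). Gas6, Cd300a and Trem2 fell by 2.46, 2.41 and 2.01, while Marco, also of this list, rose by 7.13. Liver X receptor targets gave 2 higher, 2 lower and 10 not called (camera adjusted p = 0.228), with Nr1h3 up by 1.98 and Apoe down by 1.18. Of these targets 4 were higher after median-of-ratios scaling, and 4 were lower without both libraries of replicate 2.

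Several lists of metabolism and stress rose by less. In the unfolded-protein and amino-acid stress list, 18 of 25 rose and 1 fell (median 0.68, camera adjusted p = 3.16e-07, adjusted p = 0.247 with an estimated correlation). Herpud1 rose by 2.06 and Atf3 fell by 1.59. Of 20 NRF2 targets and antioxidant genes, 12 rose and 1 fell, and 13 rose when adjusted over the list alone (median 0.40, camera adjusted p = 1.27e-05, adjusted p = 0.326 with an estimated correlation). With the replicate block, 2 genes of each of these lists were lower in place of 1, while in the NRF2 list 0 were lower after median-of-ratios scaling or without both libraries of replicate 2. Fth1, the ferritin heavy chain gene, went from 7062 ± 499 to 22450 ± 1345 FPKM. Of 26 glycolysis and hypoxia genes, 14 rose and 3 fell (median 0.37, camera adjusted p = 0.000145, adjusted p = 0.381 with an estimated correlation), with Hk2 up by 1.60 and Bnip3l down by 0.98. Of 35 respiratory chain subunit genes, 13 rose, 1 fell and 21 were not called (median 0.13, camera adjusted p = 6.02e-05, adjusted p = 0.389 with an estimated correlation), and 11 rose when adjusted over the list alone. With median-of-ratios scaling 24 of them were higher and 0 lower. Cholesterol synthesis genes had 7 of 23 higher and 1 lower (median 0.13, camera adjusted p = 0.0328, adjusted p = 0.694 with an estimated correlation), led by Mvd at 1.09, and 11 were higher after median-of-ratios scaling. Without PBS replicate 1 that list missed the threshold (0.069), as it did without K7M2-EV replicate 1 (0.0779) or 2 (0.0614) and with quantile normalization (0.051).

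Macrophage lineage genes were mostly higher, with 10 of 16 higher and 3 lower (median 0.56, camera adjusted p = 0.00036, adjusted p = 0.5 with an estimated correlation). Adgre1, which encodes the surface marker F4/80, went from 170 ± 27.2 to 1824 ± 183 FPKM and the lysozyme gene Lyz2 from 3746 ± 401 to 10860 ± 903 FPKM. Complement genes split into 6 higher and 4 lower of 12 (median 0.39, camera adjusted p = 0.027, adjusted p = 0.524 with an estimated correlation). C3 rose by 5.67 and Cd93 fell by 1.55, and the list missed the threshold without PBS replicate 2 (0.0739), with quantile normalization (0.155) and after median-of-ratios scaling (0.102). Among 15 checkpoint and immunosuppressive genes, 7 rose and 7 fell (camera adjusted p = 0.349). Cd274, which encodes PD-L1, went from 14.4 ± 1.79 to 69.9 ± 6.21 FPKM. Lgals3, the galectin-3 gene, fell from 523 ± 50.7 to 86.9 ± 7.41 FPKM and the ectonucleotidase gene Entpd1 from 8.59 ± 1.52 to 0.601 ± 0.0121 FPKM.

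Matrix and angiogenic factors gave 7 higher, 12 lower and 7 not called of 26 (median -0.77, camera adjusted p = 0.591), with Mmp14 up by 3.95 beside Mmp9. Plau, also of this list, fell by 4.31. The osteoclast list had 5 higher and 7 lower of 13, a median of -0.37 and a mean of 0.29, so that median and mean differ in sign (camera adjusted p = 0.846). Acp5, the tartrate-resistant acid phosphatase gene, went from 8.53 ± 0.475 to 93.3 ± 19.2 FPKM, while Atp6v0d2, also of this list, fell by 4.14 on the log2 scale. The p53 and apoptosis list had 3 higher and 11 lower of 17 (median -0.54, camera adjusted p = 0.128), with Trp53inp1 down by 1.77 and Fas up by 1.60. Of 21 immediate-early genes, 4 rose and 9 fell (camera adjusted p = 0.905). Ier3 rose by 2.49 and Klf2 fell by 1.33. Egr2 had a value of -1.75 and was not called without PBS replicate 1 or 3 or K7M2-EV replicate 1 or 2, with values from -1.84 to -1.35. It also lost the call with no filter (adjusted p = 0.0505) and without both libraries of replicate 1 (0.114) or 3 (0.0973).

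**Figure D3:**
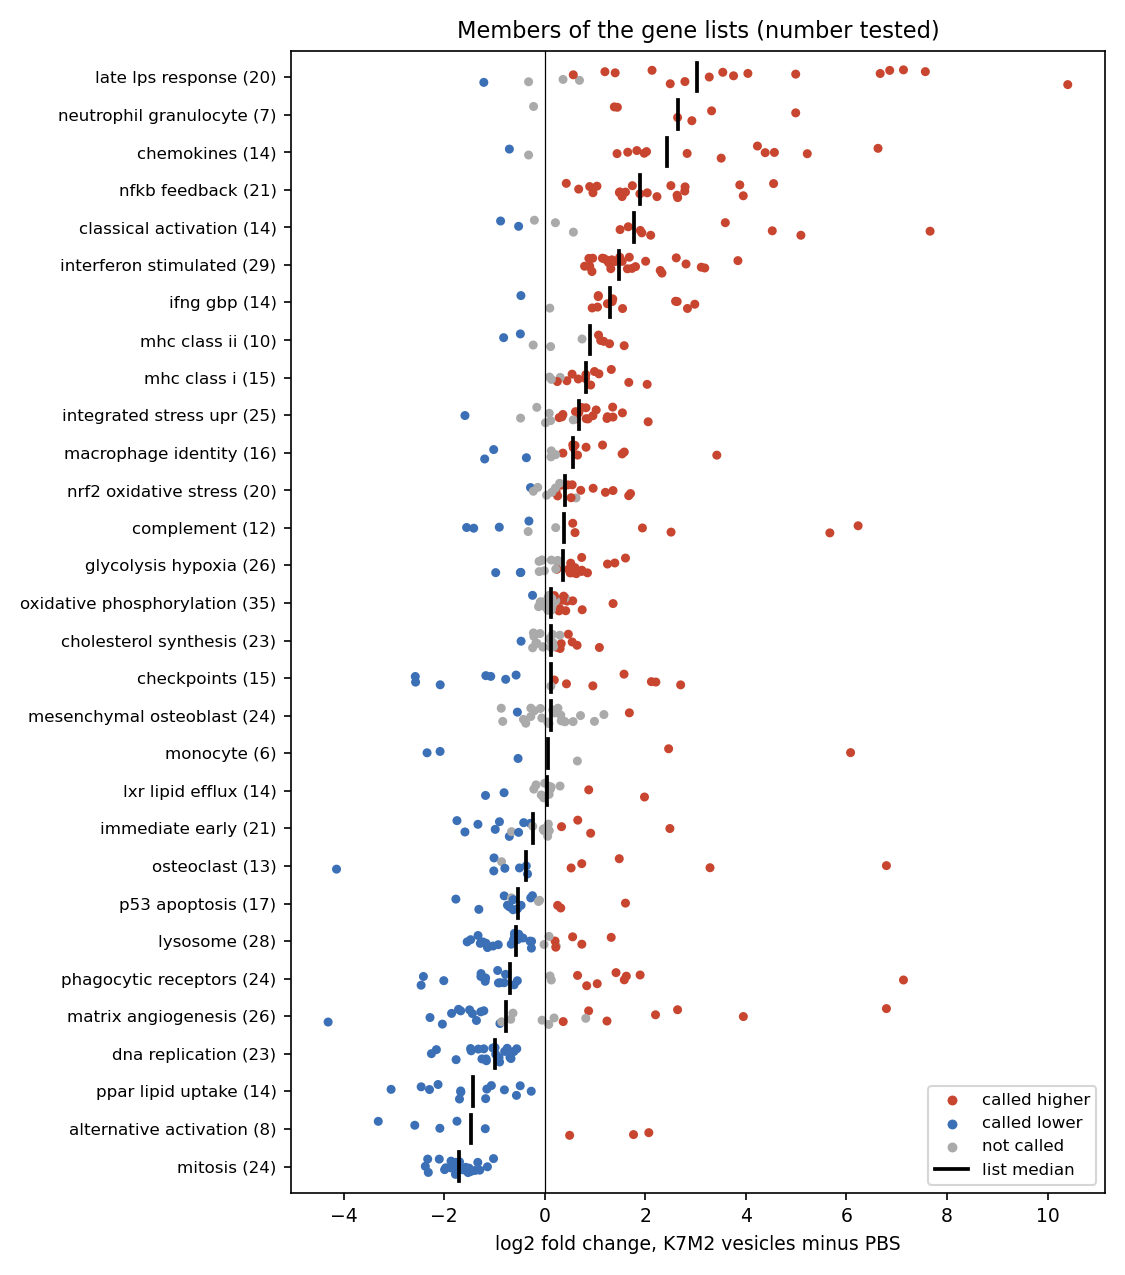
Log2 fold changes (horizontal axis, K7M2 vesicles minus PBS) of the members of 30 gene lists (vertical axis, number of tested genes in brackets), with members called higher in red, lower in blue and not called in grey. The black bar is the list median, which runs from -1.71 for mitosis to 3.03 for the endotoxin-induced genes.

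Lists of other cell types were measured as well. Mesenchymal and osteoblast genes, a list that also covers osteosarcoma cells, had 1 of 24 higher, Lox, and 1 lower, Runx2 (median 0.12, camera adjusted p = 0.228). Lox lost its call without both libraries of replicate 1 (adjusted p = 0.0705) or 3 (0.0843). Col1a1, a collagen gene, was at 98.1 ± 49.2 FPKM with PBS and 205 ± 130 FPKM with vesicles and was not called (adjusted p = 0.134). With the replicate number as a block, 9 of these genes were higher and 8 lower, and Col1a1, Col1a2 and Sparc were called (adjusted p = 0.00118, 0.00321 and 0.0194). Summed over the list, replicate 2 held 895 FPKM with PBS and 1160 FPKM with vesicles, against 371 to 496 FPKM in the other libraries. Among 7 neutrophil genes, 6 rose (median 2.64, camera adjusted p = 1.07e-05, adjusted p = 0.104 with an estimated correlation). These 7 passed the filter, of 15 members with values. Some, such as Lcn2 and Trem3 (PBS means of 0.0548 and 0.13 FPKM), passed it only through their vesicle libraries. The filter thus favoured members that rose, and the count and p-value are partly its product. Lcn2, also in the endotoxin list, and S100a8 rose by 4.99 and 3.32, while S100a9, named after its values were seen, was at 0.783 ± 0.688 and 0.517 ± 0.640 FPKM and was not called. Of 6 monocyte genes, 2 rose and 3 fell (camera adjusted p = 0.639), with Hp up by 6.08 and S100a4 down by 2.34, and with the replicate block 3 were higher and 2 lower. Too few members passed the filter to test the other 4 lists. Of these genes Pf4 and Ppbp of the platelet list rose by 2.02 and 2.14, Ighm of the lymphocyte list fell by 2.55, and 1 dendritic and 1 mast cell gene were not called. The dendritic gene, Fscn1, named after its values were seen, was called with the replicate block (log2 fold change 0.36, adjusted p = 0.00745).

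**Figure D4:**
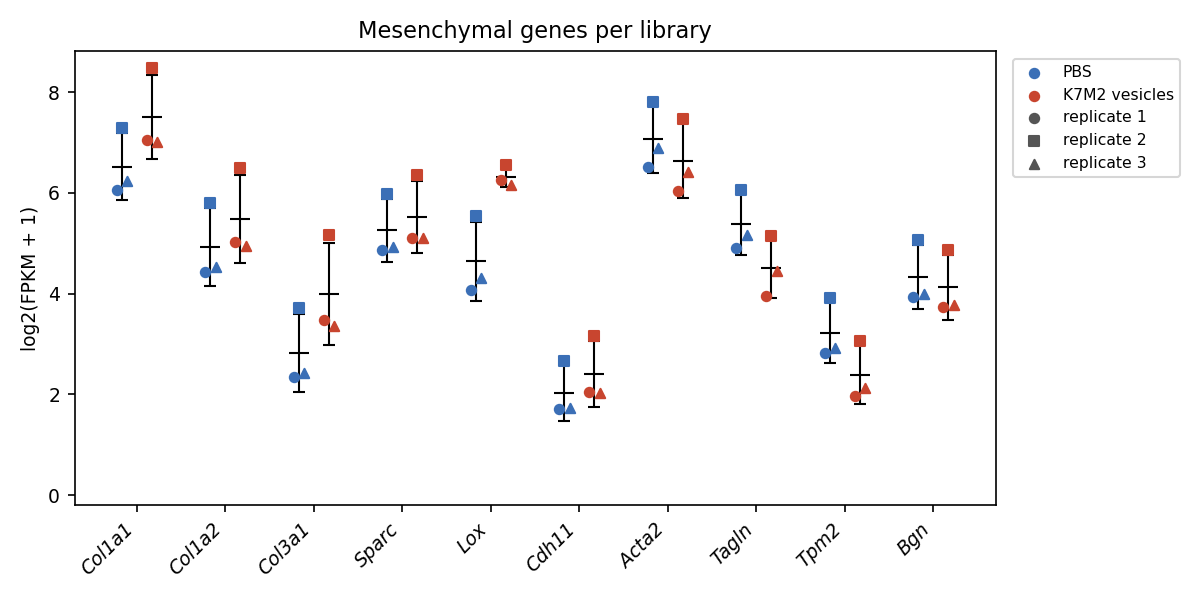
Expression of 10 mesenchymal genes (horizontal axis) as log2(FPKM + 1) (vertical axis) in each library, with PBS in blue, K7M2 vesicles in red and the replicate number shown by the symbol. Black bars give the mean and SD of 3 libraries, and replicate 2 is highest in both groups, with Col1a1 at 155 and 354 FPKM.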

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

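Alternatives were planned before the data were examined, except median-of-ratios scaling, rescaling to protein-coding reads, voom on approximate reads and leaving out both libraries of a replicate, which were chosen after seeing the data. Those that need counts (size factors and a second count test, voom on counts, count filters) were not run, because the values are FPKM. No list call and no call of a gene named by the rule changed sign. The balance of higher and lower calls turned with median-of-ratios scaling, to 3445 higher and 3376 lower. It did not turn with rescaling to protein-coding reads (2459 and 4526) or voom (2370 and 4645). Counts of higher genes ran from 1993 to 2416 and of lower genes from 3896 to 4281 without each library in turn. The counts moved by over 1.5 times with a log2 fold change of at least 1 (600 and 893) and without both libraries of replicate 3 (1531 and 2847), which leaves fewer samples. Without both libraries of replicate 2, 2365 and 4195 genes were called. With the replicate block, 2495 and 4787 were called, the MHC class II list reached 0.00982, and Col1a1, Col1a2 and Sparc were called among the named genes. It changed no other call of a list or of a gene named by the rule.

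With an estimated inter-gene correlation, adjusted p was 0.5 for macrophage identity, 0.156 for classical activation, MHC class I, NF-κB feedback and PPAR lipid uptake, 0.0724 for chemokines, and 0.198 for interferon-stimulated genes. It was 0.326 for interferon-γ GTPases and NRF2, 0.524 for mitosis, DNA replication and complement, and 0.381 for glycolysis. It was 0.389 for oxidative phosphorylation, 0.694 for cholesterol synthesis, 0.69 for lysosome, 0.247 for the stress response and 0.104 for neutrophil genes. MHC class II gained its call with no filter (0.0205) and without both libraries of replicate 2 (0.0198), and ranged from 0.0262 to 0.235 without single libraries (called without PBS replicate 1, 0.0395, or K7M2-EV replicate 2, 0.0262). Cholesterol synthesis missed the threshold with quantile normalization (0.051) and without both libraries of replicate 1 (0.138), and ranged from 0.00702 to 0.0779 without single libraries. Complement missed it with quantile normalization (0.155) and median-of-ratios scaling (0.102), and ranged from 0.0142 to 0.0739. The mesenchymal list passed it with no filter (0.0406), and ranged from 0.0214 (without PBS replicate 2) to 0.991. Checkpoints passed with no filter (0.0468) and p53 genes with quantile normalization (0.0194). Without both libraries of replicate 2, 3 lysosomal genes were higher in place of 5, and 9 mesenchymal genes were higher and 5 lower. The cause was not tested. Over all lists and alternatives, called or not in the main analysis, the side of the threshold was the same in 505 cases, a call was gained in 9 and lost in 26. For named genes the numbers were 2350, 6 and 40. Camera sets a list against other genes, while limma's fry asks whether its members shift together in 1 direction. For lists not called by camera, unadjusted fry p was 0.000137 for p53, 0.000276 for alternative activation and 0.00138 for phagocytic receptors. It was 0.00167 for monocyte, 0.00273 for matrix, 0.00826 for osteoclast and 0.0109 for checkpoint genes. It was 0.0195 for immediate-early genes, 0.0338 for liver X receptor targets, 0.294 for MHC class II and 0.902 for mesenchymal genes. Depth limits genes under 1 FPKM, where a 2 kb gene has at most 51.4 reads.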

Other observations

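Genes in this paragraph were chosen after their values were seen. Of 66 genes of the clustered histone families that passed the filter, 64 were lower with vesicles and none higher, with a median log2 fold change of -2.12 (limma, adjusted p under 0.05). The median was -1.97 after median-of-ratios scaling, and 64 were also lower with the replicate block and without replicate 2. Hist1h3h fell from 397 ± 77.9 to 65.6 ± 29.4 FPKM and the linker histone gene Hist1h1b from 141 ± 29.1 to 20.7 ± 13.5 FPKM. These genes share reads with near-identical copies, so single values are uncertain. The membrane protein genes of the Ms4a family rose in 6 of 7 cases, and Ms4a6d went from 51.8 ± 3.30 to 450 ± 71.0 FPKM. Cd38, an ectoenzyme gene, rose from 0.143 ± 0.0911 to 36.0 ± 1.89 FPKM and Gpr18 from 1.02 ± 0.220 to 25.7 ± 2.78 FPKM. Of 9 Toll-like receptor genes tested, 3 were higher (Tlr2, Tlr1 and Tlr6, by 2.79, 2.66 and 0.83 on the log2 scale), 2 lower (Tlr13 and Tlr3, at -1.24 and -0.26) and 4 not called. Tlr3 was not called after median-of-ratios scaling or quantile normalization, and Tlr8 was called higher after the former. Tlr7 was called higher without both libraries of replicate 2. Tlr4, not called, was at 17.2, 2.31 and 2.89 FPKM in PBS replicates 1 to 3 and at 1.22, 1.06 and 1.26 FPKM with vesicles. Gm47299, an annotated miRNA gene of 80 nt on chromosome 12 (69361179 to 69361258), was at 36625, 18650 and 0.487 FPKM in PBS replicates 1 to 3 and at 27065, 0.564 and 0.519 FPKM with vesicles.

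The tests in the following paragraphs were all chosen after the results were seen. The 6 libraries form 10 splits into groups of 3, and only 1 split, the real one, called 7026 genes. The highest other split called 1. With 10 splits the share cannot go under 0.1. Among the splits that part all 3 replicate pairs, the others called at most 1 gene. Every split but the real one mixes both treatments in each group, so the difference between treatments widens the spread within its groups. Few calls were thus bound to follow, and they do not measure what chance would give.

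The first pattern is the rise of genes induced by bacterial endotoxin, 16 of the 20 fixed. Median-of-ratios factors ran only from 0.9424 to 1.075 over the libraries. A difference in library scaling of that size is too small to account for a list median of 3.03. After this scaling the median was 3.17, which with such factors could hardly have turned out otherwise and is no separate test. Endotoxin in the vesicle preparation and an effect of the vesicles themselves cannot be told apart, because no vesicle-free preparation or endotoxin measurement is among the groups. Both predict the 16 rises, and the vesicle effect, which the design names, was not tested separately.

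The second pattern is the presence of mesenchymal transcripts in all libraries. RNA brought by the vesicles is argued against as their main source, since the median PBS-to-vesicle ratio of the list was 0.882. In both groups 23 of 24 members were highest in replicate 2. More stromal cells in the replicate 2 cultures stay open as a source, since that replicate was picked for these high values and the count is no separate test of it. Within replicate pairs 9 members were higher and 8 lower. For the 9 that were higher, vesicle RNA cannot be told apart from a change in the cells, since no vesicle RNA was measured.

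The third pattern is the rise of neutrophil markers. Of the 15 members of the fixed list with values, below the filter or not, 6 had all vesicle libraries above all PBS libraries. For 1, Cxcr2 (means of 0.116 FPKM with PBS and 0 FPKM with vesicles), they were all below, and 8 members overlapped. Chance gives 5% in each direction. Of the 13009 genes tested 63.8% did not overlap, but that share counts both directions and only genes that passed the filter. A like share, of all genes with the vesicle libraries above, was not taken. Without it the 6 are not read as a sign of a change particular to this list. S100a8 went from 3.07 ± 0.186 to 39.5 ± 2.04 FPKM, while S100a9 was at 0.783 ± 0.688 and 0.517 ± 0.640 FPKM and Ngp and Retnlg stayed under 1 FPKM in every library. Granulocytes in the treated cultures and induction in the macrophages by the vesicle treatment cannot be told apart from these 6 rises, because the members moved apart and most of the others lie near the floor. Lcn2 is the 1 marker shared with the endotoxin list.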
